A study of Caenorhabditis elegans with 2 samples.

How the data were processed

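The material was total RNA of mixed-stage N2 worms. Per the labels' protocols, first-strand cDNA was made with Superscript III and an oligo-dT primer, each 3′ UTR was amplified with a transcript-specific forward primer, recombined into a Gateway vector and transformed into bacteria, and the inserts of 6432 minipools were amplified again with vector primers, pooled, gel purified and read by pyrosequencing. The forward primer of each gene fixes the 5′ edge of its product and the oligo-dT primer its 3′ edge. An oligo-dT primer can also start inside A-rich RNA, and PCR and cloning favour short products, so neither the number nor the length of the products measures transcript abundance. The labels describe 2 runs, and the interval list is recorded for the minipool run. Whether reads of the other run entered it is not given in the sources used here. It was treated as a group of 1 library, so no comparison between groups and no test across replicates was made.

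The deposited file is a list of 4818 intervals with 6 columns and no header. The start and end are genomic positions in nt. The authors' score column, deposited as the fifth column, holds 0 in each row and the strand column holds a plus sign in each row, and both were treated as placeholders and not used. The name column holds the same word throughout. The file therefore gives no read count, gene, strand or splicing. How reads were assembled into contigs, the aligner, any filter and the genome build are not given in the sources used here. The intervals were found to be sorted, free of duplicates and free of overlaps. No interval was shorter than 96 nt.

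The annotation was Ensembl release 115 on assembly WBcel235. Its numbering was compared with that of the file before any use. In each 1 Mb window, intervals that held a stop codon of a protein-coding gene were taken, and the offset was taken as the difference, divided by 2, between the median distance from edge to stop codon on plus-strand and on minus-strand genes, which cancels the stretch before the stop codon that the primer adds. At least 3 intervals per strand and distances under 120 nt were used. As a second measure, all intervals of a 3 Mb window were moved by up to 6000 nt either way and the overlap with annotated 3′ UTRs was counted. Because the offset changed along the chromosomes, coordinates were not converted. The annotation was used by position only in the leading windows of each chromosome with an offset of at most 5 nt, which held 777 intervals. The other 4041 intervals entered only the lengths, gaps and counts per chromosome. Numbers of protein-coding genes per chromosome came from the same annotation.

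An interval was given to a protein-coding gene when it covered at least 10 nt of its stop codon and 3′ UTR, or when its 5′ edge lay at most 60 nt before the end of the stop codon. Where several genes met this, the one with its stop codon near the edge was taken if there was only 1, and otherwise the interval was given to none. With the planned overlap of 1 nt, 18 intervals over both strands were given to no gene, against 16 at 10 nt and 14 at 50 nt. The limit on the offset, the window size, the 60 and 10 nt distances and the way of naming were chosen after the data had been looked at. The way of naming was changed once after its results were seen, from overlap alone to overlap or stop codon, which raised the named genes from 585 to 595. The first window of chromosome V lay at the limit itself, with an offset of −5 nt. The strand is that of the gene. Ends of a gene at most 20 nt apart were joined. Interval lengths are genomic and include any intron. The length after the stop codon was taken only from intervals that started near it. Shares have exact Clopper-Pearson 95% intervals, and medians have percentile intervals from 10000 bootstrap draws over genes or intervals. Gene lists, 17 in number, of 110 single symbols besides symbol families, were fixed by name before the data were examined, and 2 of the symbols (lss-4 and cdk-6) had no gene of that name. For lists with at least 3 named genes, the median length was placed among 10000 random lists of the same size. The text names, by a rule also fixed before the data were examined, the genes with the most ends, the 5 longest and 5 shortest, the longest member and the member with most ends of each such list, and, in place of overlapping contigs on opposite strands, which the file cannot hold, the 5 longest intervals over 2 genes. Of the genes this rule takes, 1 is not reported here. Other genes named, such as members of the lists and of the coding intervals, were chosen after their values were seen.

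The functions were tested on simulated data, in which 4576 intervals were made from annotated genes. Their offset was 0 in the first 4 Mb of each chromosome and rose by 20 nt with every further 4 Mb. The intervals came from the same annotation that names them, each started within the 60 nt limit before a stop codon, and overlapping ones were left out. All of this favours correct names, and intervals named without a stop codon near the edge were not simulated. The offset in the 24 windows with a true offset of 0 was recovered with a median error of 1.12 nt and a largest error of 5 nt, no chromosome's part ran past the first true offset, and 100% of 943 named intervals got the gene they were made from. Steps of 20 nt lie far above the limit of 5 nt, so a gradual drift near that limit, as in the file, was not simulated. True offsets above 20 nt were underestimated, so larger shifts are given only from the overlap search. Of 40 random lists of 20 genes, 0 fell outside the central 95% of random lists, and 20 of 40 did once made 60 nt longer.

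Planned analyses of polyadenylation signals, of their presence at proximal and distal ends and of A-rich sequence after the ends need the genome sequence, and splicing needs alignment blocks. They were not done here. Alternatives covered the joining distance, the distance to annotated ends, the overlap that counts, the limit on the offset, the window size, the way genes are named and the random lists. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.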

Results

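The series was designed to find forms of the 3′ untranslated regions (3′ UTRs) of Caenorhabditis elegans, the part of the messenger RNA between the stop codon and the poly(A) tail. Total RNA from mixed-stage N2 worms, the laboratory wild-type strain, was reverse transcribed from an oligo-dT primer, amplified with a forward primer for each transcript, cloned, and read by pyrosequencing. The labels describe 2 sequencing runs of these RACE (rapid amplification of cDNA ends) clones. The first pooled PCR products of 6432 minipools, each the mixed bacterial transformants of 1 cloning reaction. The second held 49152 barcoded products from single colonies and 5952 minipools without barcodes. The interval list used here is recorded for the first run. Whether reads of the second run also entered it is not given in the sources used here, and no separate list of the second run was analysed here. With 1 list there is no replicate, so no value below has a replicate error. The read depth is unknown, because the file gives positions only. Intervals in brackets after shares are exact binomial 95% confidence intervals and cover the number of intervals or genes counted, that is counting error only.

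The list held 4818 intervals that covered 1024415 nt on the 5 autosomes and the X chromosome. No pair overlapped. The median interval was 183 nt long (bootstrap 95% interval 181 to 186), the interquartile range was 136 to 262 nt, and lengths spanned 96 to 839 nt. Chromosome III gave 32.4 intervals per 100 annotated protein-coding genes and chromosome I gave 30.0, whereas chromosome V gave 16.0, against 24.1 over all 6 chromosomes. Chromosome V thus held 16.5% of the intervals (15.5 to 17.6) but 4994 of the 19973 genes. Products needed a forward primer for the transcript, and which genes had one was not known here. Numbers per annotated gene may therefore reflect the choice of targets. Intervals on the X chromosome were the longest, with a median of 199.5 nt (185 to 209.5), and the 5 autosomal medians lay between 178 and 185 nt. The X median stood at percentile 99.995 of 10000 random sets of as many intervals, and that of chromosome V at percentile 3.55. Of 3 equal parts of the covered range of each chromosome, the middle part held between 39.9% (X, 36.2 to 43.6) and 48.0% (IV, 44.4 to 51.5) of its intervals.

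**Figure D1:**
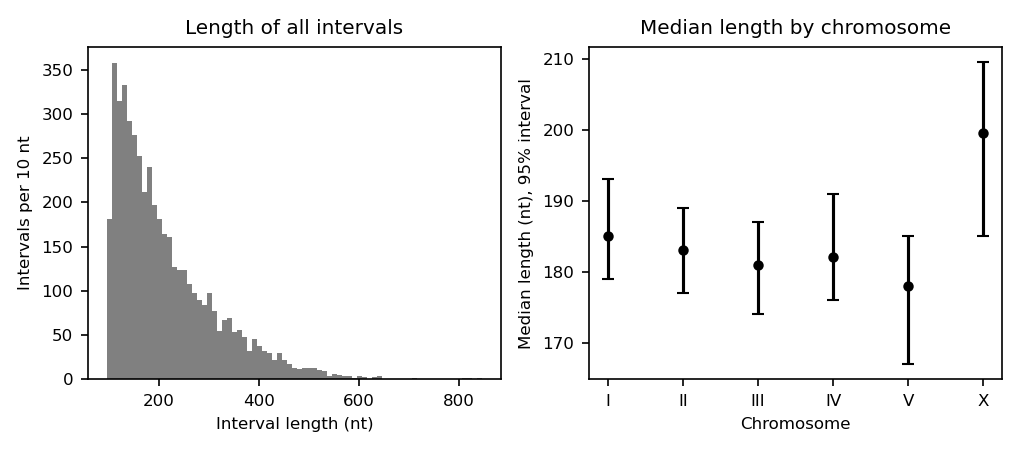
Left, number of intervals per 10 nt of length over all 4818 intervals. Right, median interval length in nt per chromosome (points) with bootstrap 95% intervals (bars), on an axis that does not start at 0; the X chromosome has the highest median, 199.5 nt.

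Gene names could be given only where the file's numbering matched that of the annotation, assembly WBcel235. The shift that best laid the intervals on annotated 3′ UTRs grew from window to window along chromosomes II, III and X. On chromosome III it went from 10 nt in the first 3 Mb to 120 nt past 12 Mb, and on chromosome IV from 5 to 37 nt. Past 18 Mb of chromosome V the best shift was 4605 nt. It laid only 33.8% of the interval bases on 3′ UTRs, against 23.4% without a shift. Best shifts in the other windows of chromosome V laid 51.4% to 70.4% there, so 1 shift may not describe the last window. In the leading part of each chromosome the numberings differed by at most 5 nt per 1 Mb window. These parts were the first 8 Mb of chromosome I, 3 Mb of IV, 2 Mb of V, and 1 Mb each of II, III and X. They held 777 intervals, 16.1% of the file. All genes, strands and distances below refer to these parts, and all coordinates are in the file's own numbering, whose build is not given in the sources used here.

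**Figure D2:**
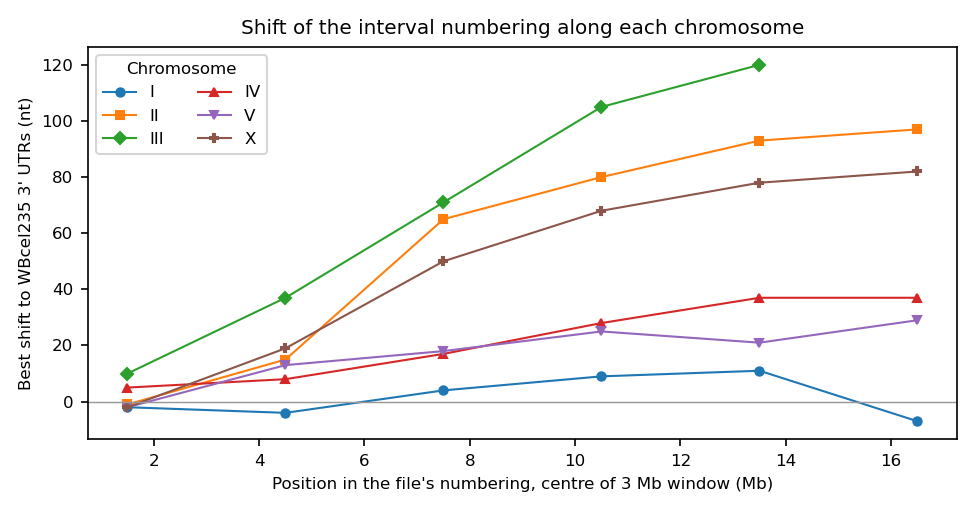
Shift in nt (vertical axis) that gave the largest overlap of the intervals with annotated WBcel235 3′ UTRs, per 3 Mb window (horizontal axis, window centre in Mb) and chromosome (symbols). Chromosome III reaches 120 nt; the last window of chromosome V, at 4605 nt, is left off the axis.

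Most intervals in these parts lay at 3′ ends of protein-coding genes. Of the 777, 609 (78.4%, 75.3 to 81.2) were given to 1 gene by its stop codon or 3′ UTR, 59 of which also covered the 3′ end of a gene on the opposite strand, and these named 595 genes, with 314 intervals on plus-strand and 295 on minus-strand genes. In 501 of them the 5′ edge lay up to 60 nt before the end of the stop codon, with a median of 32 nt (31 to 33) and an interquartile range of 27 to 39 nt, within the last coding sequence. From the stop codon to the end of the interval the median, over the longest interval of 500 genes, was 146.5 nt (136 to 158), with an interquartile range of 106.75 to 214.5 nt and a range of 58 to 666 nt. The longest intervals belonged to T22C1.1 (chromosome I, 7937608 to 7938317, 710 nt, of which 666 nt followed the stop codon), vpr-1, which encodes the worm's VAPB-related MSP-domain protein (I, 5868268 to 5868907, 640 nt), plin-1, a perilipin of lipid droplets (I, 7058532 to 7059167, 636 nt), rps-10 (I, 4583871 to 4584483, 613 nt) and the globin gene glb-33 (V, 1356332 to 1356942, 611 nt). The shortest was that of F56F4.8 (I, 6150393 to 6150493), with 63 nt after the stop codon, followed by mus-81, a structure-specific endonuclease gene (I, 4267137 to 4267238), Y38F2AR.12, Y39G10AR.16 and Y55B1AR.2 at 102 nt each. Ties were broken by identifier, and Y65B4BR.1 and dod-19 also had 102 nt. In mus-81, 64 nt followed the stop codon, and the end lay 0 nt from the annotated one.

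The 3′ ends were compared with the annotated transcript ends of the same genes. Of 501 ends, 309 (61.7%, 57.3 to 66.0) lay within 20 nt of one, and the median difference was 0 nt with an interquartile range of −14 to 8 nt. A further 113 ends (22.6%, 19.0 to 26.5) lay more than 20 nt upstream of the nearest annotated end and 79 (15.8%, 12.7 to 19.3) more than 20 nt downstream. For 28 of these 79 the nearest model ended at the stop codon and so had no 3′ UTR. gld-2, which encodes a cytoplasmic poly(A) polymerase of the germline, was one of them, with 508 nt after the stop codon (I, 6385036 to 6385592). Some other downstream ends belonged to intervals that also covered the 3′ end of a gene on the opposite strand. Examples were arl-13 (481 nt downstream, with rla-1) and lmd-2 (347 nt, with rpl-4). As the file gives no strand, such an edge may belong to the other gene's product. Upstream ends, given as negative distances from the nearest annotated end, included those of unc-15, the paramyosin gene (−277 nt), cdc-25.1, a cell cycle phosphatase gene (−165 nt), and myo-1, a myosin heavy chain gene of the pharynx (−164 nt). cpsf-1, a subunit of the factor that cleaves pre-mRNAs before polyadenylation, ended 0 nt from it. Whether the annotation drew on the same clones is not given in the sources used here, so the comparison is not known to be independent.

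**Figure D3:**
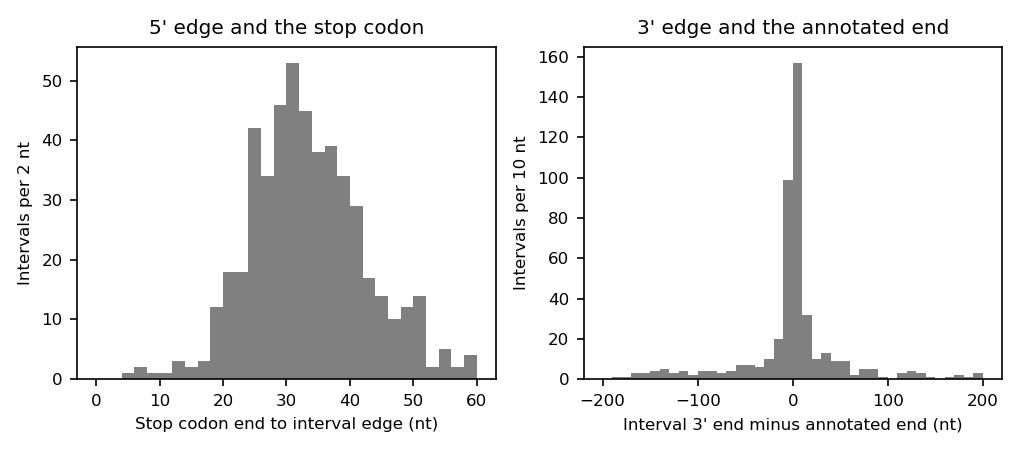
Left, distance in nt from the 5′ edge of an interval to the end of the stop codon for 501 intervals, per 2 nt. Right, 3′ end of the interval minus nearest annotated transcript end in nt, per 10 nt, for the 451 intervals within 200 nt (50 lie farther out and are not drawn); the median over all is 0 nt.

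The clones were made to find the forms of each 3′ UTR. In the deposited intervals, 13 of 595 genes (2.18%, 1.17 to 3.71) had more than 1 end. klp-20, which encodes a kinesin-2 motor subunit of cilia, had 3 (III, 227515 to 227765, 228603 to 228817 and 230430 to 230581), and the other 12 had 2 each. Without chromosome I, 7 genes had more than 1 end. The ends of a gene lay between 165 and 5949 nt apart. The widest were those of tftc-1 (5949 nt apart), Y108G3AL.2 (3641 nt), klp-20 (2816 nt from the first to the last), ptpn-22 (2808 nt), the zinc transporter gene zipt-15 (1149 nt), Y71F9B.6 (749 nt), pals-23 (623 nt) and trak-1 (472 nt). In csk-1, the gene of the worm's C-terminal Src kinase, the first interval started 29 nt before the end of the stop codon and ended 232 nt after it (I, 80315 to 80576), and the other ended 420 nt further on (I, 80820 to 80996). cmd-1, the calmodulin gene, had ends 344 nt apart.

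In 11 of these 13 genes at least 1 interval started at a stop codon, but in only 1, tftc-1, did each of them. When genes were named only by a stop codon near the 5′ edge, the share with more than 1 end was 0.200% (0.00506 to 1.11), 1 of 500 genes. The 2 intervals of tres-1 were 1 nt apart (I, 6070404 to 6070567 and 6070569 to 6070713) and those of plin-1 26 nt apart, and in 4 of the 14 gaps within these genes (klp-20, Y108G3AL.2, trak-1 and plin-1) both edges lay within 10 nt of annotated exon edges, so a further interval need not be a further end. Forms that start at the same stop codon and differ in length overlap, and the file holds no overlapping intervals, so such forms cannot be counted in it.

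Of the gene lists fixed in advance, ribosomal protein genes differed in the way the intervals lay. Here and in the lists below, counts cover listed genes only, and only intervals given to the gene itself. For example, intervals over the 3′ ends of rpl-4 and nuo-6 were given to other genes (lmd-2 and cutl-6), and that over pbs-4 to none. Of 17 listed ribosomal protein genes in these parts, 6 were given an interval at their 3′ end (35.3%, 14.2 to 61.7). In 0 of 6 (upper limit 45.9%) did it start within 60 nt of the stop codon, against 501 of 603 (83.1%, 79.8 to 85.99) of the other named intervals. They started between 87 nt (rpl-24.1) and 541 nt (rps-10) upstream, and only 36 nt (rps-27) to 71 nt (rpl-13 and rps-10) followed the stop codon. The rpl-19 interval ended 49 nt and the rpl-17 interval 39 nt after it. Their median length, 182.5 nt, lay at percentile 45.2 of random lists of the same size. This difference was noticed in the data and not planned. No interval of the file was shorter than 96 nt, and the median start near a stop codon was 32 nt before its end. A product that started there and ended 36 to 49 nt after the stop codon would be too short to be listed. The contrast with the other named intervals is thus partly set by the shortest length in the file, and cannot show another way of cloning.

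All 3 listed muscle structure genes in these parts had a 3′ interval, and these 3 were long. They measured 440 nt for unc-15 (I, 7376881 to 7377320) and 429 nt for unc-89, a giant protein of the sarcomere M-line (I, 4090392 to 4090820). That of myo-1 measured 379 nt (I, 7259110 to 7259488). Their median, 429 nt, lay at percentile 99.4 of 10000 random lists of 3 named genes, and that of the sequence after the stop codon, 393 nt, at percentile 99.7. Collagen genes of the cuticle lay at the other end. Of 32 in these parts, 4 had a 3′ interval (12.5%, 3.51 to 29.0), with a median of 123.5 nt at percentile 1.59. The sequence after the stop codon was 84 nt in col-101, 89 nt in col-53 and 95 nt in col-48, with a median at percentile 5.21, and the longest collagen 3′ interval was that of col-104 at 226 nt. These percentiles describe 3 or 4 genes of 1 list and are not tests. Collagen genes resemble each other, and how reads with several matches were placed is not given in the sources used here.

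The medians of the remaining lists with at least 3 named genes lay within the central 95% of random lists. Translation factor genes had a median of 264 nt (percentile 89.5, 4 of 7 genes), the longest being ife-2, an eIF4E cap-binding protein gene, at 357 nt (X, 381385 to 381741). Neuropeptide genes had a median of 241 nt (percentile 79.0, 3 of 10 genes), with nlp-62 at 263 nt, flp-24 at 241 nt and nlp-64 at 140 nt. Proteasome genes had 150 nt (percentile 21.4, 3 of 6 genes), with 141 nt after the stop codon in both pas-3 and rpn-8 and 114 nt in rpt-4. Nuclear receptor genes, a large family of transcription factors in this worm, rarely had a 3′ interval, 2 of 50 (4%, 0.488 to 13.7) against 595 of all 2828 annotated protein-coding genes in these parts (21.04%, 19.6 to 22.6). The 2 were nhr-23, a regulator of moulting, with 171 nt after the stop codon, and nhr-204 with 139 nt. Which genes were given a forward primer was not known here. Shares of annotated genes with an interval, in this and the other lists, therefore mix the choice of targets with their recovery. Each of the other lists with a 3′ interval had it in a single member. They were unc-13, a synaptic vesicle priming factor gene (428 nt, 1 of 1 listed synaptic gene in these parts), and cpsf-1 (1 of 1 listed cleavage and polyadenylation factor). Further single members were cdc-25.1 (1 of 1 listed heterochronic or microRNA target gene), gld-2 (1 of 5 listed germline genes) and vha-10 (1 of 4 listed vacuolar ATPase genes). The last were nuo-2 (1 of 3 listed respiratory chain genes) and ceh-93 (1 of 6 listed homeobox genes). In the 6 lists with at least 3 named genes, each gene had 1 end, and the mean lay between percentiles 43.8 and 46.9 of random lists. A mean of 1 is the lowest possible and most random lists tied with it, so these percentiles reflect the ties and decide nothing. None of 4 listed small GTPase genes had a 3′ interval, which allows a share of up to 60.2%. No listed histone or vitellogenin gene lay in these parts.

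Of the 777 intervals, 75 covered 3′ ends of genes on both strands. In 59 of them only 1 gene had its stop codon near the edge, and the interval was given to it. The other 16 (2.06%, 1.18 to 3.32) were given to neither gene, and in 12 of these a stop codon lay within 60 nt of each edge. All but 2 of the 16 lay on chromosome I. The longest of the 16 ran 564 nt between F33E11.2 and F33E11.3 (V, 299826 to 300389). The next were those between pcbd-1 and T10B11.8 (342 nt), ears-2 and ssna-1 (323 nt), gly-2 and C55B7.11 (322 nt) and, without a stop codon near either edge, glrx-10 and Y34D9A.8 (301 nt). Other pairs were pbs-4, a proteasome subunit gene, with mrrf-1 (238 nt), and parp-1, a poly(ADP-ribose) polymerase gene, with pph-7 (212 nt). The median of the 16 was 229.5 nt, against 182 nt for intervals given to 1 gene. An interval must reach the 3′ ends of 2 genes to be among the 16, so this contrast is partly set by how they were picked. Among neighbouring intervals less than 200 nt apart in which both had a gene, 4 pairs faced each other and 3 belonged to 1 gene, and 0 of 253 pairs in the same direction and 0 of 103 facing away were that close. Between 3′ ends in the same direction or facing away lies the body of at least 1 gene, so these counts of 0 are largely set by the layout. The genes kbrl-1 and inx-14, an innexin gene, ended towards each other with 16 nt between their intervals.

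A further 114 intervals (14.7%, 12.3 to 17.4) covered at least 10 nt of a coding exon and were not given to the 3′ end of any gene, in 96 genes. Their median distance to the next stop codon was 2095 nt, with an interquartile range of 333 to 5028 nt, and 57 were coding along their whole length. Distances to the stop codon here are genomic and include introns, and 1 interval of fnip-2 had none and was left out. unc-89 held 7 of them between positions 4055403 and 4067268 of chromosome I, all fully coding and at least 10859 nt before its stop codon. lin-59 held 3, and 10 more genes held 2 each, among them unc-15, the E3 ligase gene ubr-4 and col-107. Ribosomal protein genes held 3 (rpl-13, rpl-19 and rpl-27) and rab-11.1, a GTPase gene of recycling endosomes, held 1. Of the remaining intervals, 23 (2.96%, 1.89 to 4.41) lay on annotated pseudogenes, 10 in introns of protein-coding genes, 1 on another exon, and 4 on chromosome I on no annotated gene.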

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

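The distances to annotated ends, the joining of ends, the length minimum and the matching of random lists were set before the data were examined, and the limits on the numbering, the windows, leaving out chromosome I, the other ways of naming genes and the collagen value after the stop codon were chosen after seeing the data. Of 86 alternative values, 64 stayed within the confidence interval of the reported value, within 1.5 times the reported count or on the same side of the central 95% of random lists, and 22 did not. The 64 include those that could change nothing, named at the end. The share of ends near an annotated end, 61.7% within 20 nt, was 52.3% within 10 nt and 72.9% within 50 nt. Where the numberings had to match within 3 nt, fewer intervals entered and 337 genes were named, 6 had more than 1 end and 10 intervals over both strands were given to no gene. With a limit of 10 nt more intervals entered, 927 genes were named, 31 such intervals were found and 17.5% of annotated genes were recovered. Windows of 0.5 Mb left 268 genes, 6 of them with more than 1 end, and windows of 2 Mb gave a recovery of 18.1%. Chromosome III dropped out with 2 Mb windows or the 3 nt limit, and klp-20 with it. Without chromosome I, 233 genes were named, 7 had more than 1 end, 2 intervals over both strands were given to no gene, 67.2% of ends lay near an annotated end, 11.3% of intervals lay in coding exons and 16.9% of genes were recovered. Naming genes only by a stop codon near the edge left 1 gene (0.2%) with more than 1 end, a recovery of 17.7% and 24.2% of intervals in coding exons, because intervals without such a stop codon are then not named. The collagen percentile was 5.21 for the sequence after the stop codon. The cause of the other differences was not tested. Joining ends at 5, 10 or 40 nt, or not at all, and leaving out intervals under 50 nt could change nothing, since no intervals overlap and none is shorter than 96 nt. The share of ends near an annotated end uses only intervals that start near a stop codon. Naming genes by such stop codons alone could therefore not change that share. Intended variations of read counts, A-rich sequence and polyadenylation signals were not run, as the file gives no counts and no genome sequence was used here. No paired analysis was possible because there was 1 library. The read depth and the set of genes given a forward primer are unknown, so a gene without an interval is not shown to lack the product.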

Other observations

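Of the tests below, those of coding length and of 3′ edges at exon ends were set before their result was seen, as was that of annotated shorter transcripts, and the others were chosen afterwards.

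Some intervals away from 3′ ends stood beside another interval. The 5 unc-89 intervals between 4055403 and 4056983 of chromosome I were 37 to 122 nt apart. A coding interval lay 92 nt from the 3′ interval of the same gene in rpl-19, 57 nt from the first in cmd-1 and 22 nt in knl-2, a kinetochore gene. Of the 287 pairs of neighbours in which at least 1 was given to no gene, 21 were less than 200 nt apart, and the median gap was 9350 nt.

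The median coding length over the 114 intervals in coding exons was 1918.5 nt. It lay inside 10000 draws weighted by coding length (1365 to 1945.5), the outcome set beforehand for placement by coding length. By values chosen afterwards, the intervals lay in 96 genes, against 105 to 113 in the draws. Of these genes, 38.5% also had a 3′ interval (draws 19.8 to 35.8). Both values argue against placement by coding length alone. The draws ignored expression and the choice of targets, so coding length may still play a part. Without unc-89, which held 7 against at most 5 in any draw, 95 genes stood against 99 to 106; whether genes took intervals independently stays open, since unequal expression would also lower the number of genes. The lower quartile of the distance to the stop codon, 333 nt, against a largest offset of 5 nt, argues against a numbering shift, and a 3′ edge within 10 nt of an annotated exon end in 28.9% (20.8 to 38.2), or either edge at an exon edge in 41.2% (32.1 to 50.8), argues against exons of spliced clones as the whole cause, though they may make up part. The share that ended within 20 nt of an annotated transcript end, 0%, decides nothing on shorter transcripts, because the way the class is formed leaves most such intervals out. Expression level and priming inside A-rich RNA were not tested and stay open, and no biological explanation was tested.

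The best shift rose by 110 nt along chromosome III, and it rose from window to window on 3 chromosomes (II, III and X). A constant trim of the interval edges would give 1 shift for all windows, which the spread of 110 nt argues against. Numbering on another assembly version stays open, because its test, the rise itself, is the pattern that prompted it, and no biological explanation was tested.

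The fullest 10 nt length class, from 106 nt upwards with 358 intervals, began 10 nt above the shortest interval. A minimum length set before the intervals were deposited stays open, because this value of 10 nt restates the pattern that prompted it. Loss of short products in gel purification was not tested and stays open too, and no biological explanation was tested.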
